A study of Mus musculus with 18 samples.

How the data were processed

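CUT&RUN libraries were made from sorted DP thymocytes of WT and tamoxifen-induced Satb1 KO mice. Per the labels' protocols, nuclei on Concanavalin A beads were incubated with antibody for 2 h and with pAG-MNase for 1 h, and libraries were built from about 5 ng of DNA. The submitters' processing notes name Trimmomatic 1.24, Bowtie2, SAMtools, deepTools, MACS2, R 4.12 and the mm10 build; their settings, and the control used for peak calling, are not given in the sources used here. The files are MACS2 narrowPeak lists, 1 per library, so peaks were called per sample, not on pooled samples. The authors' peak lists give a fold enrichment (ratio) at each summit, and −log10 p and −log10 q values as deposited; the summit's offset in bp is the other column used. The highest q in the lists was 0.0498. The lists hold no read numbers, so no count model was used.

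Samples were grouped by genotype and antibody from the labels, and 7 of the 18 samples had a list that was analysed. Peaks on chromosomes 1 to 19, X and Y were kept. Peaks of 1 mark were merged where they overlapped by at least 1 bp, and a list holds a merged region if 1 of its peaks overlaps it. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1. Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 represents; all 188 genes of the 12 fixed lists were found in it. The table has no strand or exons and no genome sequence was used here, so whether a region is exonic or intronic is not stated, and the planned shares of peaks at transcription starts and with a CTCF motif were not run. In place of the former, summits within 1 kb of either end of a protein-coding gene were counted, a measure chosen after seeing the data.

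Pile-up and background per peak were solved from the deposited fold and −log10 p under the caller's Poisson model. The pile-up came out whole, with the −log10 p met within 0.001, in 4000 of 4000 peaks tried per list, and the lowest 1% of local backgrounds is given as the depth proxy. Wilson and exact intervals cover counting error only. SMC1A peak numbers and shares at CTCF were compared with an exact two-sided permutation test, which cannot go below 0.333 with 2 against 2. Lost and gained regions were counted and set beside the other 2 splits of the 4 lists and beside the number expected if lists were independent. CTCF overlap and gene lists were tested with Fisher's exact test, two-sided, on regions within 20 kb of gene bodies, with Benjamini-Hochberg adjustment over the 12 lists and a percentile among 10000 random gene lists matched on the number of regions. Windows of 1 Mb with a mean of 5 or more peaks were tested with limma on log2((peaks + 0.5) per 1000000 peaks of the library), with a mean-variance trend; the fitted prior degrees of freedom were infinite, so every window shares 1 spread per density.

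Named regions follow a fixed rule: the 8 with the highest lower −log10 q per mark and direction, up to 4 genes (SMC1A) or 2 (CTCF) per gene list and direction in the same order, 8 genes always described, 5 shared regions, and up to 10 windows by p. A region takes the protein-coding gene whose body holds its summit, or else the nearest gene boundary within 100 kb, where the rule had named the nearest transcription start. Genes that share a region count once. Trac, Egr1 and S1pr1 rank below the first 4 of their lists for SMC1A and were named after their values were seen.

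Replicate numbers match the batch given in the labels, so they pair samples. As a check, deviations of same-numbered SMC1A libraries from their genotype mean had a correlation of 0.0031 over 1276 windows. The alternatives were −log10 q of 5 or more, lists of equal length, summits within 200 bp, overlaps of at least 0.5 of the shorter peak, other CTCF sets, other gene distances, other window settings, each replicate left out, and the replicate block.

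The steps were tested on simulated data. Of planted regions, 400 of 400 lost and 600 of 600 gained were recovered with 0 wrong. Planted regions were never missing at random from a list of their side. This checks the overlap code only, not how often a list misses a region. With 200 windows changed in both directions, the windows test called 40.0% of the 2-fold and 89.3% of the 4-fold changes that passed the filter, and 11 of 1056 unchanged windows. With the 200 changed windows all raised, it called 17.0% and 96.0%, and 33 of 1066 unchanged windows, all as lower, since division by the library total moves the rest down. With no change it called 0 of 1257. Gene list tests of 20 regions passed an unadjusted 0.05 in 2.2% of 500 unchanged lists and 76.0% of 500 lists with 4 times the odds. These regions were drawn independently at a base share near that of gains. The figures do not carry over to losses, which are rarer, or to gains that cluster at a gene.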

Results

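The series asked how induced loss of Satb1 affects thymocytes, here by mapping chromatin-bound proteins in sorted DP thymocytes of WT and Satb1 KO mice, all given tamoxifen. SATB1 is a chromatin organiser that is abundant in thymocytes. The assay was CUT&RUN, in which an antibody brings a nuclease to a protein on chromatin and the released DNA is sequenced. SMC1A is a core subunit of cohesin, the ring complex that extrudes chromatin loops, and CTCF is the zinc finger protein at which cohesin is commonly halted. Of the 18 samples of the series, 7 peak lists were analysed here, 2 WT and 2 KO for SMC1A, and 1 WT and 2 KO for CTCF. A second WT CTCF list, the H3K27ac, IgG and input samples were not analysed here. On the standard chromosomes the SMC1A lists held 19882 and 20638 peaks in WT and 28151 and 20689 in KO. The CTCF lists held 38989 peaks in WT and 55750 and 22928 in KO. Read depth is unknown from such lists, but the background pile-up implied by the peak caller's own statistics gives a proxy. It was 0.533 and 0.465 reads in the WT SMC1A libraries and 0.633 and 0.384 in the KO ones. In the CTCF libraries it was 1.02 in WT, 1.82 in KO replicate 1 and 3.28 in KO replicate 2, so the list with the fewest CTCF peaks had the highest background. The labels do not say that replicates came from separate animals. Permutation and limma p-values thus measure only the spread between these samples, which may be technical. Fisher's exact tests count regions and measure no spread between samples. A region below is lost if both WT lists and neither KO list hold it, and gained if both KO lists and neither WT list hold it; coordinates are mm10. Fold values and −log10 q of single peaks are the authors' and rank peaks only within their own list.

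Satb1, the targeted gene, lies on chromosome 17 from 51736187 to 51833290. A peak list does not measure the deletion, so these values do not check the genotype labels. Within 20 kb of the gene, both WT lists held 13 SMC1A regions, of which 4 were lost and 4 were in all 4 lists. The lost regions all lay inside the gene body. They were at 51805106 to 51805499 (−log10 q of 12.8 and 19.2 in the WT lists), 51767849 to 51768080 (7.91 and 7.51), 51782659 to 51783099 (7.02 and 22.3) and 51742637 to 51742851 (7.85 and 6.99). No SMC1A region was gained there. The WT CTCF list held 12 regions at Satb1, of which 6 were in neither KO list and 3 were in all 3 CTCF lists. CTCF peaks in the 1 Mb window from 51000001 numbered 17 in WT, 34 in KO replicate 1 and 4 in KO replicate 2. Per 1000 peaks of the list these were 0.436, 0.610 and 0.174, so the KO lists went opposite ways. The 1 Mb window that holds Satb1 and Tbc1d5 had 21 and 22 SMC1A peaks in WT and 20 and 7 in KO, a log2 density change of -1.08 ± 0.20 (SE; limma adjusted p = 9.3e-06). Without KO replicate 2 the change was -0.58 and the adjusted p 0.29, so KO replicate 2 carries that call.

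**Figure D1:**
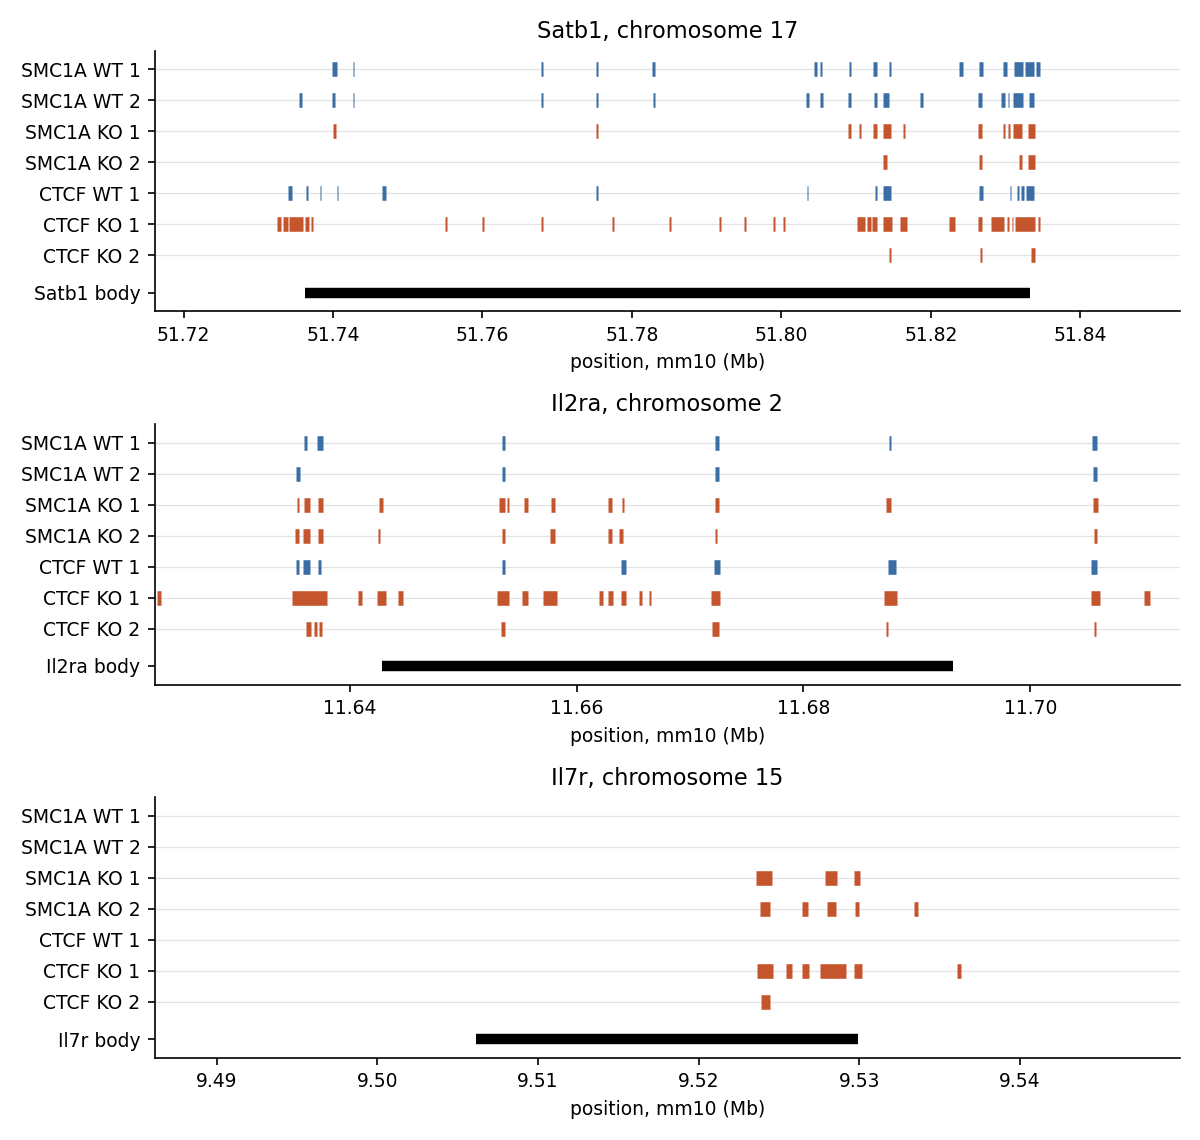
Peaks of each list (rows; WT blue, KO orange) along Satb1, Il2ra and Il7r, with position in Mb of mm10 on the x axis and the gene body as a black bar, 20 kb shown on either side. Satb1 had 13 SMC1A regions in both WT lists and 4 in both KO lists, while Il7r had none in WT and 3 in both KO lists.

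Across the genome the 4 SMC1A lists merged into 35221 regions, of which 12326 (35.0%) were in all 4. Lost regions numbered 616, or 4.15% of the 14846 regions in both WT lists, and gained regions numbered 2277, or 13.1% of the 17319 regions in both KO lists. The strongest lost regions lay in Gm5591 (chromosome 7, 38525388 to 38525725) and St8sia1 (chromosome 6, 142937602 to 142937945), near Gm52481 on chromosome Y, near Jup and Ephx1, near Ywhaq, and in Arhgap21 and Unc5cl. The strongest gained regions lay near Pls3 (chromosome X, 75744334 to 75746076), near Kdr, in Vmp1, near Ifngr1, the interferon gamma receptor gene (chromosome 10, 19565601 to 19566455), in Ikzf3 (chromosome 11, 98476598 to 98478070) and near Tmem196. The other 2 of the 8 strongest gains were over 100 kb from any protein-coding gene, on chromosome 17 at 52278496 to 52278895 and on chromosome X at 50611360 to 50613181. Strength here is the rank by −log10 q. The gain near Tmem196 had a fold of only 2.19 and 2.37 in the KO lists, against 10.9 or more for the others. The genotype split separated more regions, 2893, than the split by batch, 1410, or the crossed split, 1363. With the top 19882 peaks of each list it separated 2639 regions, against 1169 and 1120, with 1149 lost and 1490 gained, so the ratio of gains to losses went from 3.70 to 1.297. Within batches, 2834 regions were in WT alone and 11211 in KO alone in batch 1, but 5892 and 5804 in batch 2, where the 2 lists are nearly equal in length and gains did not outnumber losses. Counts of lost and gained regions depend on each list: they were 3101 and 3624 without WT replicate 1, 2358 and 3646 without WT replicate 2, 2269 and 4232 without KO replicate 1, and 867 and 8704 without KO replicate 2. Membership of lists treated as independent would give 1016 lost and 3050 gained regions, 0.606 and 0.746 of which were seen; the batch split gave 0.415 and 0.215 of its expectation and the crossed split 0.224 and 0.369.

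**Figure D2:**
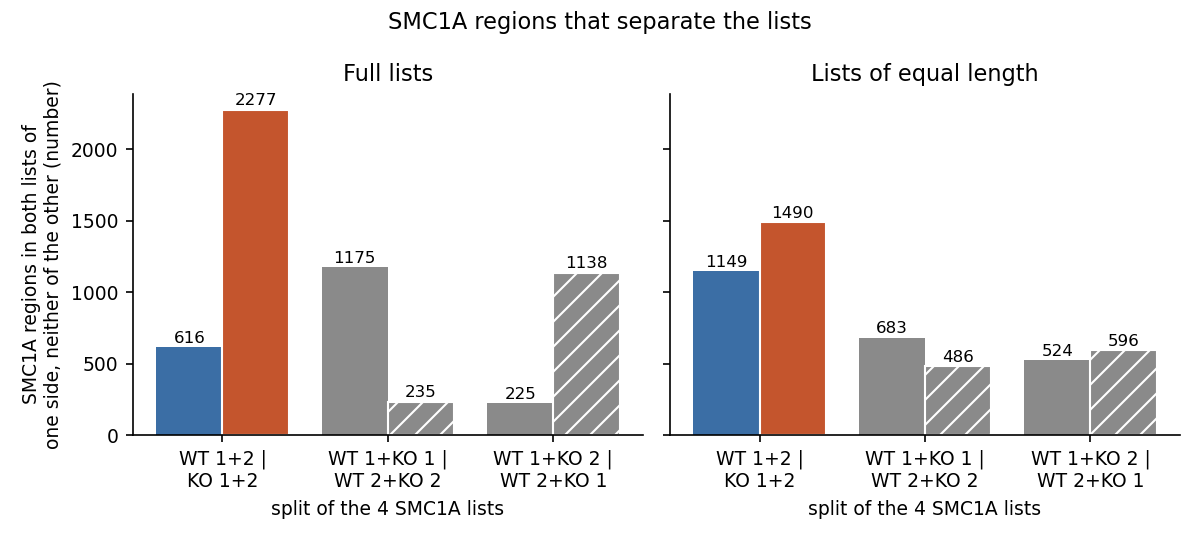
Number of SMC1A regions (y axis) held by both lists of one side and neither of the other, for the 3 ways to split the 4 lists (x axis), with full lists and with the top 19882 peaks of each. The left bar of each pair counts the side named first. The genotype split gives 616 and 2277 regions in full lists and 1149 and 1490 at equal length.

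Gains of SMC1A were concentrated at 2 of the 12 gene lists fixed before the data were examined. At regulatory T cell genes, 8 of 22 regions of both KO lists (36.4%) were gained, against 12.0% at all other protein-coding genes, an odds ratio of 4.21 (95% interval 1.53 to 10.8; Fisher's exact test, Benjamini-Hochberg adjusted p = 0.017; percentile 99.39 among 10000 random lists). They fell at 4 of the 12 genes: 4 regions at Il2ra, which encodes the high-affinity chain of the IL-2 receptor, 2 at Ikzf2 (Helios), and 1 each at Ctla4 and Icos. The strongest were at Il2ra on chromosome 2, 11662771 to 11663141 (−log10 q of 17.3 and 12.8 in the KO lists), and at Ikzf2 on chromosome 1, 69681012 to 69681412 (19.7 and 11.3). At Foxp3, the lineage factor of regulatory T cells, the single SMC1A region was in all 4 lists. At cytokine and effector locus genes, 7 of 15 regions (46.7%) were gained, an odds ratio of 6.44 (1.99 to 20.3; adjusted p = 0.011; percentile 100). They fell at 6 of the 15 genes, among them 3 regions at Il7r, the IL-7 receptor, 1 each at S1pr1, which guides T cell egress, and at Klf2, and 1 shared by Il5 and Rad50, neighbours in the type 2 cytokine locus. Regions are not independent replicates, so these tests describe the lists. Leaving out KO replicate 2, so that the longer KO list stands alone, gave odds ratios of 1.84 (adjusted p = 0.20) and 2.98 (adjusted p = 0.12), and without WT replicate 2 the regulatory T cell list stood at 2.84 (adjusted p = 0.078). Within 100 kb of the genes the odds ratios were 1.50 and 1.68, both with an adjusted p of 0.48, within gene bodies alone 21.1 (adjusted p = 3.7e-05) and 9.87 (adjusted p = 0.0062), and with peaks of −log10 q 5 or more they were 3.40 (adjusted p = 0.15) and 3.74 (adjusted p = 0.24).

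**Figure D3:**
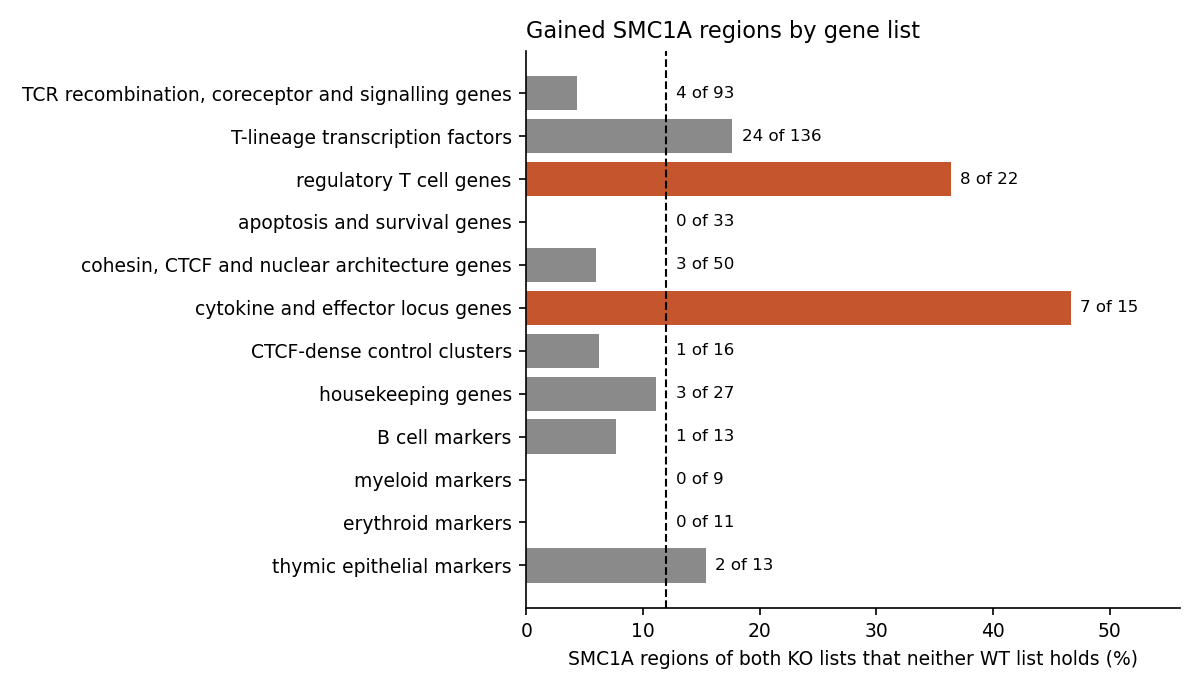
Percent of the SMC1A regions of both KO lists that neither WT list held (x axis), for the 12 gene lists (y axis), with the counts beside each bar. Orange marks an adjusted p under 0.05 and the dashed line the 12.0% at other genes; regulatory T cell genes reached 36.4% and cytokine and effector genes 46.7%.

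The other lists did not pass for gains. T-lineage transcription factors had 24 of 136 regions gained (17.6%, adjusted p = 0.11), at 13 of 31 genes, among them 4 at Ikzf3 (Aiolos), 3 at Tox, 3 at Foxp1 and 2 at Id3. Within gene bodies alone that list passed, with an odds ratio of 2.32 (adjusted p = 0.0062). Genes of T cell receptor recombination, coreceptors and signalling had 4 of 93 regions gained (4.30%), an odds ratio of 0.328 (adjusted p = 0.065), among them at Trgc1, at Trbc1 and Trbc2, and at Cd247. With lists of equal length its lower share passed (1 of 83, odds ratio 0.124, adjusted p = 0.026), as it did without WT replicate 2 (0.281, adjusted p = 0.0041). Apoptosis and survival genes had 0 of 33 (Fisher's exact test, unadjusted p = 0.028, adjusted p = 0.084), and within 100 kb 3 of 92, an odds ratio of 0.230 (adjusted p = 0.049). Their odds ratio turned to 2.20 with peaks of −log10 q 5 or more (adjusted p = 0.34) and to 1.10 without WT replicate 1 (adjusted p = 1). Cohesin, CTCF and nuclear architecture genes had 3 of 50 (Top2b, Mau2 and Lmnb1), CTCF-dense control clusters 1 of 16 (H19) and housekeeping genes 3 of 27 (Polr2a, B2m and Actb). Markers of other cell types had 1 of 13 for B cells (Blnk), 0 of 9 for myeloid cells, 0 of 11 for erythroid cells and 2 of 13, both near Prss16, for thymic epithelium.

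For losses 0 lists passed (Fisher's exact test; 0 at an unadjusted p under 0.05). T-lineage transcription factors lost 8 of 132 regions (6.06%, against 3.82% at other genes), 4 of them at Satb1 and 1 each at Lef1, Foxp1, Zbtb7b (the CD4-lineage factor ThPOK) and Egr1, for an odds ratio of 1.63 (95% interval 0.683 to 3.33; Fisher's exact test, adjusted p = 1). With lists of equal length it lost 21 of 130, an odds ratio of 2.40 (Fisher's exact test, adjusted p = 0.013). The list also passed with peaks of −log10 q 5 or more (11 of 93, 2.89, Fisher's exact test, adjusted p = 0.036). Its odds ratio was 1.85 without WT replicate 1, 1.81 without WT replicate 2, 1.69 without KO replicate 1 and 2.05 without KO replicate 2. Each is above the 1.63 of full lists. These settings leave 1 list in a genotype, so only the size is given, and the missing p does not mean that the list failed there. Satb1, the targeted gene, is on this list, with 4 of its 13 regions lost in full lists. How many losses lay at Satb1 under these alternatives was not counted, and the list was not tested without it. T cell receptor and coreceptor genes lost 5 of 102 regions, at Cd247, Ccr9, Cd8a, Cd3e and Trac. The region near Cd8a, at 71360606 to 71361105 on chromosome 6, had a −log10 q of 15.5 and 3.72 in the WT lists. Regulatory T cell genes lost 1 of 17 (Lrrc32), apoptosis genes 1 of 31 (near Bid), cohesin and CTCF genes 3 of 47 (Pds5b, Ctcf and Esco1), CTCF-dense clusters 2 of 18 (Igf2 and Pcdhga1), and thymic epithelial markers 1 of 10 (Aire). Cytokine and effector genes lost 0 of 5, housekeeping genes 0 of 24, B cell markers 0 of 12, myeloid markers 0 of 11 and erythroid markers 0 of 12. Around Rag1 and Rag2, the recombinase genes, Cd4, Bcl6 and Smc1a no SMC1A region was lost or gained. Cd4 kept its 5 regions in all 4 lists.

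Density in 1 Mb windows differed in 76 of 1276 windows (limma, Benjamini-Hochberg adjusted p under 0.05), with 51 higher and 25 lower in KO. The lowest p belonged to a decrease on chromosome 5, 15000001 to 16000000, from 23 and 26 peaks in WT to 4 and 2 in KO (log2 change -3.15 ± 0.25 SE). That window holds Speer4d, Speer4c, Gm17019, Gm21149, Gm21190, Gm21083 and Cacna2d1. On chromosome X, 50000001 to 51000000, with Stk26 and Frmd7, peaks went from 4 and 7 to 33 and 33 (2.28 ± 0.21). The window on chromosome 14 from 69000001, which holds Slc25a37, Entpd4 and Entpd4b among others, went from 12 and 12 to 50 and 28 (1.35 ± 0.18). Whether reads map to 1 place only in this window or in that on chromosome 5 was not checked. The chromosome 13 window from 19000001, which holds the T cell receptor gamma constant gene Trgc1, went from 3 and 3 to 19 and 12 (1.90 ± 0.29), and the chromosome 10 window from 19000001, with Ifngr1 and Tnfaip3, a brake on NF-κB signalling, from 21 and 17 to 48 and 39 (0.92 ± 0.15). Windows on chromosome 11 from 90000001 (Hlf, Mmd), X from 75000001 (Mtcp1, Pls3), 8 from 88000001 (Cyld, Nod2) and 14 from 53000001 were also higher in KO. Splits by batch and crossed gave 0 windows each in limma, with 18 and 15 at an unadjusted p under 0.05, against 242 for genotype. By the threshold alone 63.8 would be expected. The other splits put 1 WT and 1 KO list on each side, so differences by genotype widen their spread. They fall below that number and are no neutral yardstick for the 242. With lists of equal length 0 windows passed in limma (168 at an unadjusted p under 0.05; lowest adjusted p 0.264), though the log2 changes stayed about as large, at -3.69 on chromosome 5, 2.28 on X from 50000001, 1.33 on 14 from 69000001 and -1.24 at Satb1, and with each library's median set to 0 it was 4, those on chromosomes 5, X from 50000001, 14 from 69000001 and 13 (adjusted p of 0.0154 or less). Leaving out a library gave 50 (WT replicate 1), 51 (WT replicate 2), 19 (KO replicate 1) and 22 (KO replicate 2). Of the windows named here, that on chromosome 5 was not tested with peaks of −log10 q 5 or more, where its mean was under 5 peaks. That on chromosome 8 had an adjusted p of 0.0882 without WT replicate 1 and 0.106 without KO replicate 1 in limma. That on chromosome 14 from 53000001 had 0.0553 without WT replicate 2 and 0.453 without KO replicate 1, and that on X from 75000001 had 0.0584 without KO replicate 2.

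**Figure D4:**
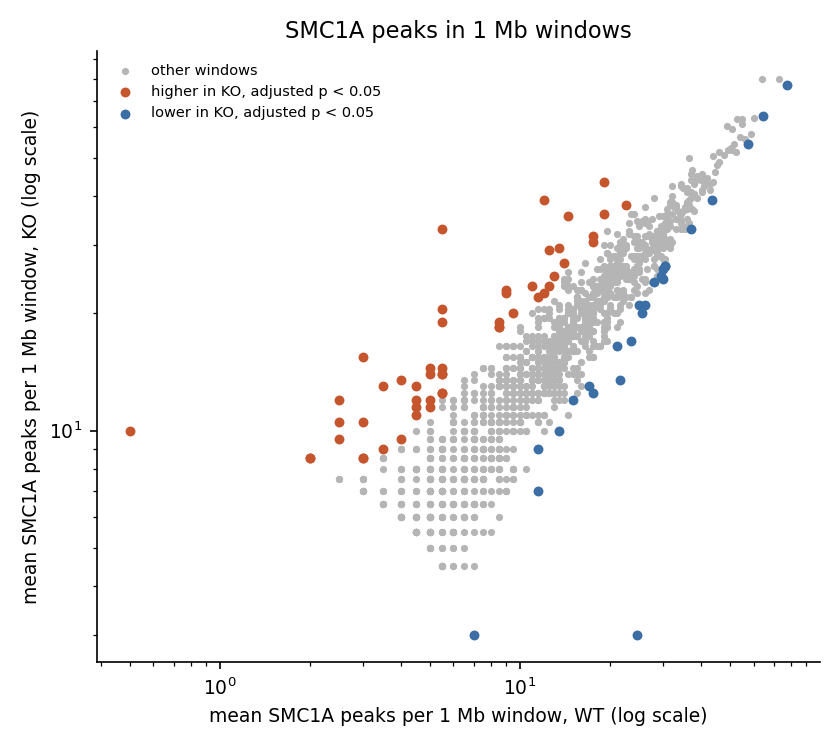
Mean number of SMC1A peaks per 1 Mb window in WT (x axis, log scale) and KO (y axis, log scale), 2 lists each, for the 1276 windows tested. Orange points are the 51 windows higher in KO and blue points the 25 lower; the chromosome 5 window lies at the lower right.

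For CTCF only 1 WT list was analysed here, so WT replicates could not be compared and no test across samples was run. The 3 lists merged into 63947 regions, of which 17272 were in all 3. Of the 36200 regions of the WT list, 6834 (18.9%) were in neither KO list, and 1561 regions were in both KO lists but not in WT. Among the strongest lost were 4 regions on chromosome Y, 1 of them near Gm52481, and regions near Zfp945 and Gm40035. Among the strongest gained were Cntnap2 (chromosome 6, 46833908 to 46834280), 2 regions on chromosome X within 50613967 to 50623673, and regions near Ccnh and Ccn2. The 2 that ranked highest by −log10 q lay on chromosome 9, at 3009304 to 3009645 and 3012757 to 3013080. Their folds in the KO lists were low, at 1.66 and 1.84 for the first and 1.60 and 1.63 for the second. In the fixed lists, gained CTCF regions included Il7r (chromosome 15, 9523649 to 9524626), Ikzf1, Runx1, Ikzf2, Icos, S1pr1 and Top2b, though Ikzf1 (4 lost, 1 gained), Top2b (4 and 2) and Ikzf2 (2 and 1) lost more CTCF regions than they gained; lost ones included Runx3, Prf1, Lat, Actb and a region near Cd4. Genes of cohesin, CTCF and nuclear architecture lost 31 of 100 WT regions (31.0%, against 19.1% elsewhere), with 5 of 12 at Ctcf, an odds ratio of 1.90 (1.20 to 2.95; Fisher's exact test, adjusted p = 0.056; percentile 99.14). Cd8a lost 7 of 16. For CTCF 0 lists passed for losses (1 at an unadjusted p under 0.05, by Fisher's exact test) and 0 for gains (0 unadjusted). KO replicate 1 held 80.5% of the WT regions and KO replicate 2 held 48.3%, so the counts depend on which KO list is used: without KO replicate 1, 18715 regions were lost and 3464 gained, and without KO replicate 2, 7047 were lost and 25844 gained. With the top 22928 peaks of each list, 3120 were lost and 1688 gained, while 3153 and 3898 regions were in KO replicate 1 or KO replicate 2 alone.

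SMC1A peaks lay mostly at CTCF peaks when all 3 CTCF lists were merged. The share overlapping the merged CTCF lists was 95.8% (95% Wilson interval 95.5 to 96.1) and 93.8% (93.4 to 94.1) in WT, and 95.04% (94.8 to 95.3) and 96.3% (96.1 to 96.6) in KO, against 6.80% to 7.15% for peaks moved by 100 kb. Against single CTCF lists it was 76.8% to 87.9% with the WT list and 56.7% to 66.3% with KO replicate 2, or near the merged share, 92.2% to 95.4% with KO replicate 1. The difference of 0.909 percentage points, KO minus WT, was within the spread between replicates (exact two-sided permutation test, p = 0.667, where 0.333 is the smallest 2 against 2 can give). It was -0.754 in batch 1 and 2.57 in batch 2, and without WT replicate 2 it turned to -0.104. It also turned with other CTCF sets, to -4.51 with the regions held by all 3 CTCF lists and to -7.83 with the CTCF list of the same genotype and batch. Mean SMC1A peak numbers were 20260 ± 535 in WT and 24420 ± 5276 in KO (SD, n = 2 each), a ratio of 1.21 (exact permutation p = 0.333); it was 1.42 in batch 1 and 1.00 in batch 2, and 1.19 with the replicate number as a block.

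Regions that differed between genotypes lay at CTCF less often than the shared ones, of which 12264 of 12326 (99.5%) overlapped a CTCF peak. The share was 84.4% (520 of 616) for lost regions, an odds ratio of 0.0274 (95% interval 0.0193 to 0.0386; Fisher's exact test p = 3.0e-87), and 98.7% (2248 of 2277) for gained regions, an odds ratio of 0.392 (0.248 to 0.633; p = 1.1e-04). Shared regions were also stronger. Their median −log10 q was 12.5 and 11.5 in the WT lists, against 5.18 and 4.62 for lost regions. In the KO lists it was 17.5 and 10.5, against 6.62 and 4.81 for gained regions. Regions that split the lists by batch or crosswise lay at CTCF in 93.2% to 96.3%, more than the lost and less than the gained regions. The merged CTCF set comes mostly from KO lists: against the WT CTCF list alone the shares were 66.2% for lost and 55.2% for gained regions. Both were then below the 73.6% to 75.6% of the batch and crossed splits. With peaks of −log10 q 5 or more the odds ratio of gained regions turned to 1.23 (Fisher's exact test p = 0.825), and with lists of equal length it was 0.517 (p = 0.0632). It was 0.0303 without KO replicate 1 and 0.0331 without KO replicate 2, and that of lost regions was 0.00959 without WT replicate 1, 0.0138 without WT replicate 2 and 0.0757 without KO replicate 1. Lost regions lay within 1 kb of a protein-coding gene end in 26.0% (95% Wilson interval 22.7 to 29.6) and gained regions in 17.3% (15.8 to 18.9), against 47.1% (46.3 to 48.0) of the shared ones and 27.1% to 31.3% of regions that split the lists in the other 2 ways. SMC1A summits lay at gene ends in 38.2% and 36.8% in WT and 31.7% and 35.1% in KO, a difference of -4.05 percentage points (exact permutation p = 0.333), or -2.25 with lists of equal length.

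SMC1A lists of the same genotype overlapped more than those of different genotype. The Jaccard index of merged regions was 0.604 between the WT SMC1A lists and 0.570 between the KO lists, and 0.527 to 0.562 between genotypes; same-batch pairs of different genotype averaged 0.544 and the remaining pairs 0.544. For CTCF it was 0.470 between WT and KO replicate 1, 0.441 between WT and KO replicate 2 and 0.330 between the KO lists, whose lengths differ most; with lists of equal length these were 0.670, 0.558 and 0.586. Of the 5 regions ranking highest in all 7 lists, 1 lay near Parp3 (chromosome 9, 106476628 to 106477471, SMC1A fold of 58.5 and 66.1 in WT and 83.8 and 55.8 in KO), 1 near Cr2, 1 near Gm32856 and 2 over 100 kb from a protein-coding gene.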

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

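Of the tests in this part, the ratio of gains to losses with lists of equal length, the shares at WT and KO replicate 1 CTCF lists of equal length and the marker genes of other cell types were chosen after their results were seen, and the regulatory T cell and effector lists were joined after their shares were seen.

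Peaks on unplaced or random sequences lie outside the comparisons. They numbered 47 in CTCF WT replicate 1, 62 in CTCF KO replicate 1 and 39 in CTCF KO replicate 2. In the SMC1A lists they numbered 37 and 52 in WT and 29 and 22 in KO.

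SMC1A gains outnumbered losses 3.70 to 1 in full lists, but within batch 2, whose lists are nearly equal in length, 5892 regions were in WT alone and 5804 in KO alone. The sides of the batch and crossed splits differed more, at 5.00 and 5.06 to 1, each time in favour of the side with KO replicate 1, the longest list. With lists of equal length the genotype ratio was 1.297 and those of the other splits 1.41 and 1.14. List length may account for most of the excess, and whether any remains cannot be told apart from it with 2 lists per genotype. A loss of Satb1 that adds SMC1A sites stays open and was not tested.

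Gained regions lay at CTCF peaks more often than lost ones. Weak peaks as the whole reason are argued against: among regions with a −log10 q of 5 or more in both lists that hold them, the lost share was 69.5% and the gained share 99.4%, a difference of -29.9 percentage points (95% interval -37.6 to -23.1). Against the WT CTCF list alone the order turned, with lost regions higher by 11.0 points (6.65 to 15.1). Before that result was seen, this order had been set down as the mark of a CTCF set made mostly of KO lists. With the WT and KO replicate 1 CTCF lists at equal length, lost regions were again lower, a difference of -17.9 points (-21.4 to -14.7). That later set still holds KO replicate 1. Its full list alone overlapped 98.2% of gained and 76.9% of lost regions, so the set cannot put this reason aside. The direction thus depends on the CTCF set. A set made mostly of KO lists, a change of CTCF itself with genotype, or a difference in quality between single CTCF libraries stays open, since only 1 WT CTCF list was analysed.

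SMC1A gains at the joined regulatory T cell and effector genes had an odds ratio of 5.03 (15 of 37 regions), but 1.58 (95% interval 0.956 to 2.51) within 100 kb of the genes. The sides of the batch split gave 2 of 25 and 0 of 20 there, against 7.00% and 1.57% at other genes. Those of the crossed split gave 0 of 21 and 2 of 24, against 1.56% and 6.70%. List length was argued against by equal lists, which gave 5.40 (2.35 to 11.8). The odds ratio was 4.27 (2.34 to 7.82) without KO replicate 1 and 2.15 (1.23 to 3.74, 27 of 57) without KO replicate 2. Regions gained in both KO lists stay gained when 1 KO list is left out, so these values do not test dependence on 1 list. At marker genes of B, myeloid or erythroid cells, which the DP sort would remove, the odds ratio was 0.229 (0.00562 to 1.37, 1 of 33 regions, at Blnk). Its upper bound lay below 5.03. At markers of thymic epithelial cells, which the sort would also remove, it was 1.33 (0.144 to 6.12, 2 of 13, near Prss16), and 13 regions are too few. Whether such cells would add SMC1A regions at their marker genes was not shown here, so neither value decides about them. No gene is on 2 of the 12 lists, and how many of the marker genes DP cells express was not measured here. A different mix of T cell stages in the sorted gate, or a change within DP cells after loss of Satb1, may underlie the pattern, and neither was tested.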

How the results depend on the processing

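Of the tests in this part, the CTCF overlap against the WT CTCF list alone or against WT and KO replicate 1 lists at equal length, the gene-end share and the joined gene list were chosen only after the result was seen. Of the alternatives for values that answer a comparison, 65 kept direction and side of the threshold or, for counts, stayed within 1.5 times, 34 counts moved by more, 1 became weaker and 4 reversed. Sizes differed among the 65, as with the CTCF odds ratio of gained regions, 0.392 in full and 0.0303 without KO replicate 1. Of those for single gene lists, 27 were the same, 7 weaker, 4 stronger and 2 reversed; for the joined list 7 were the same and 1 weaker. The cause was not tested except where fewer lists or peaks by construction change membership. With lists of equal length, SMC1A regions lost were 1149 and gained 1490, CTCF regions lost 3120, the CTCF odds ratio of gained SMC1A regions 0.517 (Fisher's exact test p = 0.0632), gene lists passing for losses 1, and windows 0 (limma; 168 unadjusted). With −log10 q of 5 or more, CTCF regions lost were 1947 and gained 1030, the gained odds ratio reversed to 1.23, gene lists passing were 1 for losses and 0 for gains (Fisher's exact test, 3 gained at an unadjusted p under 0.05), the apoptosis odds ratio reversed to 2.20, and windows were 18. With summits within 200 bp, CTCF regions lost were 11145. The share of SMC1A peaks at CTCF reversed to -4.51 points with CTCF regions held by all 3 lists and to -7.83 with the list of the same genotype and batch. With the replicate block, SMC1A regions lost and gained were 2834 and 11211 in batch 1 alone and 5892 and 5804 in batch 2 alone. Within 100 kb, 1 gene list passed for gains, apoptosis and survival, with fewer gains than elsewhere, and the 2 lists with more gains lost their call. Windows numbered 41 with a mean of 10 or more peaks and 4 with median scaling. Leaving out 1 list gave ranges of 867 to 3101 SMC1A regions lost and 3624 to 8704 gained, 7047 to 18715 CTCF regions lost and 3464 to 25844 gained, -0.104 to 1.92 points for the share at CTCF, 0 to 1 gene lists for losses and 0 to 2 for gains, 0.128 to 1.10 for the apoptosis odds ratio, and 19 to 51 windows; limma then takes the lone list to vary like the others. Shares of peaks at transcription starts and with a CTCF motif, with their alternatives, were not run. Read depth is not known from peak lists, so a region missing from a list may lie below its threshold, and the caller's background (0.384 to 0.633 in SMC1A, 1.02 to 3.28 in CTCF) limits what each list can show.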

Other observations

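The tests in this part were chosen only after the data were seen, except the percentiles among random gene lists. Gained SMC1A regions held a CTCF peak more often in KO alone than in WT alone, while lost regions did so about equally. With the WT and KO replicate 1 CTCF lists at an equal 38989 peaks, gained SMC1A regions held a CTCF peak in KO alone at 927 sites and in WT alone at 37. Lost SMC1A regions held one in KO alone at 73 and in WT alone at 77, an odds ratio of 26.3 (95% interval 16.3 to 43.0; Fisher's exact test over regions, which are not independent replicates). Among gained SMC1A regions, 231 of 2277 (10.1%) overlapped a gained CTCF region, against 74 of 12326 (0.600%) of the shared ones. Both marks had a gained region within 20 kb at 10 genes of the fixed lists: Il7r, Ikzf1, Ikzf2, Ikzf3, Icos, S1pr1, Tox, Tox2, Top2b and Prss16. At Ikzf1, Top2b, Tox2 and Ikzf2 more CTCF regions were lost (4, 4, 3 and 2) than gained (1, 2, 1 and 1), and at Ikzf3 2 were lost and 2 gained.

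On chromosome Y a high share of a small number of regions was lost, though its peak number was not lower in both KO lists. The SMC1A lists held 25 and 45 peaks there in WT and 32 and 23 in KO, so KO replicate 1 had more than WT replicate 1. Of its 21 SMC1A regions in both WT lists, 10 were lost (47.6%), against 4.09% on the other chromosomes, an odds ratio of 21.3 (95% interval 8.08 to 55.5). Of its 18 regions in both KO lists, 5 were gained (27.8%), against 13.1% elsewhere, an odds ratio of 2.54 (0.709 to 7.61). In the windows that changed most, CTCF peaks per 1000 of the list were 0.795 in WT and 0.161 and 0.872 in KO on chromosome 5 from 15000001 (31, 9 and 20 peaks), so KO replicate 2 was not below WT. On chromosome X from 50000001 they were 0.154 in WT and 0.753 and 1.13 in KO (6, 42 and 26 peaks).

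The comparisons named next were first set up as tests of technical explanations and are given as values alone, a choice made after their results were seen. The genotype split separated 2.05 times as many SMC1A regions as the higher of the other splits, and 2.26 times with lists of equal length. The background pile-up of CTCF KO replicate 2 was 1.80 times that of KO replicate 1. The percentile among random gene lists matched on the number of regions was 99.39 for gains at regulatory T cell genes and 100 at cytokine and effector genes; this last comparison was written down before its result was seen.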
